A study of Mus musculus with 8 samples.

How the data were processed

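The series holds 8 samples from 4 libraries of lineage-depleted, Kit-positive bone marrow cells, each library giving an RNA and a surface protein sample. There were 2 vehicle and 2 metformin libraries, all from transplanted female mice after 7 months of treatment. Per the file headers, the deposited values are UMI counts per feature and cell barcode, for 32285 genes and 2 antibody tags (CD45.1 and CD45.2), without normalization. Cell Ranger 6.1.2 and the genome build mm10 are named in the submitters' processing notes. Per the labels, CD45.1 marks Dnmt3a+/+ and CD45.2 marks cells with 1 mutated copy of Dnmt3a, which the labels write R878H in most places and R879/+ in the extract protocol. R878H is used here. The labels do not say whether a library came from 1 mouse or from a pool, so each p of a single gene or a share measures the spread between libraries. The list test camera, described below, compares the genes of a list with other genes at a preset inter-gene correlation. Its p at that setting is not a measure of the spread between libraries.

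Cells with at least 500 genes, at least 1000 gene UMIs and at most 10% mitochondrial UMIs were kept, which left 69092 of 71615 barcodes. Scrublet, as in scanpy 1.11.5, marked 5542 doublets, and 63550 cells remained: 15117 and 15697 in vehicle replicates 1 and 2, and 15899 and 16837 in metformin replicates 1 and 2. The libraries held 384810215, 395897823, 360043783 and 388129802 gene UMIs in the same order, and the kept cells had medians of 18036, 17394, 15555 and 16123 UMIs. Leiden clustering of all cells together (igraph 0.11.9) at resolution 1 gave 38 clusters. A cluster took the name of the class with the most markers among its 10 leading genes, provided that this class had 1 of the 2 highest marker averages and at least 3 detected markers. In this way 28 clusters were named, and the ending -like marks that the classes come from RNA alone.

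The planned genotype call, a mixture of 2 normal distributions on the log2 ratio of the tags over a whole library, gave 0 mutant and 1450 wild-type cells, since the tag background differs between clusters. The mixture was therefore fitted within each library and cluster, with 1 shared SD, on cells within 2.5 of the median ratio. A cluster was used where the components lay at least 2 SD apart with weights of at least 0.05 in all 4 libraries and each library had at least 50 cells. A call needed a posterior of 0.99. This rule was chosen after the tag counts were seen. It covered 16 clusters with 35824 cells (56.4% of those kept) and called 4059 wild-type and 17266 mutant cells. The clusters of T/NK-like and plasma cell-like cells also separated but were left out as mature cells. By library, 782, 566, 1401 and 1310 wild-type and 7264, 6516, 1536 and 1950 mutant cells were called in vehicle replicates 1 and 2 and metformin replicates 1 and 2.

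Shares were compared by exact two-sided permutation, with 0.333 as the smallest possible p for 2 libraries against 2, and by exact sign flips within libraries, with 0.125 as the smallest. Intervals for single libraries are exact Clopper-Pearson intervals. For genes, UMI counts were summed per library and genotype, over all called cells or over a class. These sums ranged from 8548935 UMIs (wild-type cells of vehicle replicate 2) to 122870335 (mutant cells of vehicle replicate 1) for all cells and from 2007100 to 20657104 for HSC/MPP-like cells. They were tested in edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr, Benjamini-Hochberg threshold 0.05) under R 4.3.3. Genotype comparisons had the library as a block, the change of the genotype difference with metformin was an interaction term, and metformin was compared with vehicle within each genotype. The other classes were tested where every library and genotype had at least 50 cells. Standard errors come from the edgeR fit, and SDs are between libraries.

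The 27 gene lists and the cell markers, tests, alternatives and the rule for named genes were fixed before the data were examined, with the exceptions given here and in the text. Named genes passed the threshold with an average log2 CPM of at least 3. They moved the same way in every library (genotype) or had arms that did not overlap (metformin). Predicted genes, mitochondrial and ribosomal protein genes were left out, the 10 highest and 10 lowest fold changes and up to 4 members per gene list were taken, and Dnmt3a and Ptprc were always given. Where fewer than 5 passed, the 5 genes with the smallest p are given as not passing. Not every gene that met the rule is given in the text. Lists were tested with camera (limma 3.58.1, inter-gene correlation 0.01), with camera at an estimated correlation, and with fry, each adjusted over the lists of a comparison.

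The fits were tested on simulated data with the real mean levels and depths and the dispersion trend of the fit. Genes were drawn independently, without a spread of their own and without library effects. The recovery below can therefore be higher than in the real data. Of 50 genes changed 2-fold, 49 were recovered for genotype over all cells, 35 for the interaction, 37 for metformin in wild-type and 36 in mutant cells. In HSC/MPP-like cells the numbers were 44, 24, 41 and 41, and at 1.5-fold 38, 8, 18 and 17. Between 1 and 12 unchanged genes were called per comparison. A planted list of 25 genes changed 1.5-fold was found by camera at the fixed correlation in each comparison. Its genes were drawn independently, so this does not test the fixed correlation. At an estimated correlation and adjusted over 27 lists, it passed in 1 of 8 comparisons (genotype over all cells, adjusted p = 0.00872; highest elsewhere 0.974), so a list that does not pass there can still be changed.

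The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, each tag called apart, leaving out each library, no library block, the replicate number as a block, equal cells per class, leaving out genes near Ptprc, Leiden resolution 2 (51 clusters), no doublet removal and stricter cell filters. Each tag called apart was fitted within library and cluster unless a whole library is named, a setting chosen after the tag counts were seen. Posteriors of 0.9 and 0.5, mixture weights, the mature clusters, a crossed replicate pairing, equal cells per class for the interaction and for each arm, equal cells per cluster within a class, and sums without use of the tags were added after the data were seen. Calculations in Python 3.11.15 used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and statsmodels 0.14.6, and plots matplotlib 3.10.9. Sequence reads were not analysed here.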

Results

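Lineage-depleted, Kit-positive bone marrow cells of transplanted female mice were profiled by CITE-seq, which reads the RNA and the antibody tags of each cell together. Each of the 4 libraries (2 vehicle, 2 metformin, 7 months of treatment) held Dnmt3a+/+ cells, marked by CD45.1, beside cells with 1 copy of the Dnmt3a R878H mutation, marked by CD45.2. Dnmt3a is a DNA methyltransferase, and metformin is a glucose-lowering drug. The comparisons below address the share of mutant cells, the cell classes they occupy, and the genes that differ by genotype and by treatment. After filtering, 63550 cells remained, of which 35824 lay in clusters where the tags separated. Of these, 17266 were called mutant and 4059 wild type. The most frequent classes among all kept cells were early erythroid/megakaryocyte progenitor-like cells (18279) and late erythroid-like cells (11081). Basophil/mast-like (7642), HSC/MPP-like (6599, the class with stem and multipotent progenitor markers), early granulocyte-monocyte progenitor-like (6383), megakaryocyte-like (4620) and monocyte progenitor-like cells (4017) followed. The late erythroid-like cells and most early erythroid cells carried too little tag contrast for a genotype call.

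Mutant cells made up 91.1% ± 1.22 (SD, n = 2 libraries) of the called cells in vehicle and 56.1% ± 5.32 (n = 2) in metformin, a difference of -35.1 percentage points. By library, the share was 90.3% in vehicle replicate 1 (exact Clopper-Pearson 95% interval 89.6 to 90.9), 92.0% in vehicle replicate 2 (91.4 to 92.6), 52.3% in metformin replicate 1 (50.5 to 54.1) and 59.8% in metformin replicate 2 (58.1 to 61.5). The intervals cover counting error only. All 6 called classes had a lower mutant share in both metformin libraries than in both vehicle libraries. HSC/MPP-like cells went from 88.1% ± 3.44 in vehicle to 56.6% ± 12 in metformin, and early granulocyte-monocyte progenitor-like cells from 92.5% ± 0.99 to 50.6% ± 0.88. Megakaryocyte-like cells (93.1% ± 1.43 and 63.3% ± 14.6) and basophil/mast-like cells (89.4% ± 0.55 and 55.2% ± 2.11) had the same order, as did early erythroid/megakaryocyte progenitor-like (93.2% ± 1.57 and 51.9% ± 10.5) and monocyte progenitor-like cells (92.8% ± 3.36 and 57.4% ± 19.1). The differences exceeded the spread between libraries of 1 arm. The exact two-sided permutation p was 0.333, the smallest that 2 libraries against 2 allow. The tags separated less in the metformin libraries, where 31.3% and 38.0% of the cells in the called clusters received a genotype against 90.1% and 79.3% in vehicle. Mixture weights, which use every cell of these clusters, put the mutant share at 87.2% in vehicle and 53.4% in metformin. Weights can lie near 50% where the tags separate poorly. Cluster 0, left out with 0.99 and 1.12 SD in vehicle replicates 1 and 2, gave 54.1% and 51.0%. Among called clusters in metformin, the weakest separation was 2.03 SD (cluster 12, replicate 1, 60.7% mutant). The strongest was 3.80 SD (cluster 11, replicate 2, 54.1% mutant).

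**Figure D1:**
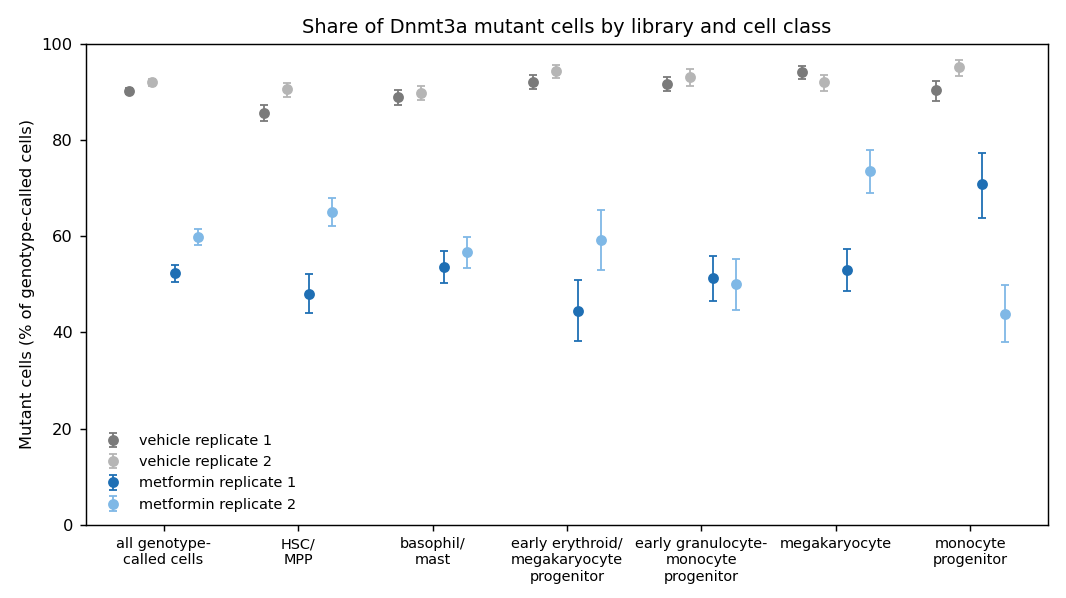
Share of mutant cells among genotype-called cells (y axis, percent) for all called cells and 6 cell classes (x axis). Each point is 1 library and each bar its exact 95% binomial interval; the vehicle libraries lie at 85.7% or above in every class and the metformin libraries at 73.6% or below.

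Without use of the tags, HSC/MPP-like cells were 11.9% ± 0.18 (SD, n = 2) of kept cells in vehicle and 8.95% ± 0.39 in metformin. Megakaryocyte-like cells were 8.42% ± 0.79 and 6.21% ± 0.63, and early granulocyte-monocyte progenitor-like cells 9.36% ± 0.48 and 10.7% ± 1.35. Each of these 3 differences separated the arms, with an exact permutation p of 0.333, the smallest possible. Basophil/mast-like (11.1% ± 0.69 and 12.9% ± 2.83), early erythroid/megakaryocyte progenitor-like (27.8% ± 0.32 and 29.6% ± 2.35) and late erythroid-like cells (17% ± 0.13 and 17.8% ± 2.29) differed by less than the spread between the metformin libraries. Within libraries, megakaryocyte-like cells were a larger part of mutant than of wild-type cells in 4 of 4 libraries, at 16% ± 1.71 against 12.4% ± 4.57 (SD, n = 4; mean difference 0.49 log2 odds). The exact sign-flip permutation p was 0.125, the smallest that 4 libraries allow, and 0.75 after adjustment over 6 classes. At a posterior of 0.5 the order held in 3 of 4 libraries, with 13.8% of mutant and 14.3% of wild-type cells in vehicle replicate 2. HSC/MPP-like cells were 24.2% ± 7.77 of mutant and 27.1% ± 2.97 of wild-type cells (-0.26 log2 odds; exact p = 0.5). Among called mutant cells, early erythroid/megakaryocyte progenitor-like cells were 17.4% ± 1.38 in vehicle and 7.32% ± 0.31 in metformin (-1.41 log2 odds, exact p = 0.333), and among wild-type cells 12.9% ± 2.31 and 8.71% ± 1.41 (-0.64 log2 odds). With calls at a posterior of 0.5, which gives every cell of the called clusters a genotype, these differences were -0.19 and 0.06 log2 odds.

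Across all called cells, the platelet genes Itgb3 and Gp1bb and the chaperone gene Clu rose most among the named genes in mutant against wild-type cells, and Ctse and Ccl5 fell most. Log2 fold changes are given ± SE from the fit to 4 libraries. Clu, which encodes a secreted chaperone, rose by 0.74 ± 0.12, Itgb3, a subunit of the platelet fibrinogen receptor, by 0.71 ± 0.09, and Gp1bb, part of the platelet receptor for von Willebrand factor, by 0.68 ± 0.10. The lysosomal glycoprotein gene Cd68 rose by 0.50 ± 0.08, the water channel gene Aqp1 by 0.41 ± 0.06, the fructose kinase gene Khk by 0.35 ± 0.06, Selenom by 0.34 ± 0.05, the actin crosslinker gene Flna by 0.26 ± 0.03 and Ifi27 by 0.25 ± 0.03. Ctse, which encodes the protease cathepsin E, fell by 2.19 ± 0.08, from 54.1 ± 3.28 CPM (UMI counts scaled to a common total; SD, n = 4) in wild-type to 11.9 ± 2.13 in mutant cells, with an edgeR adjusted p of 5.2e-06. The chemokine gene Ccl5 fell by 1.78 ± 0.27, the TNF receptor family member Tnfrsf18 by 0.60 ± 0.09, Oser1 by 0.56 ± 0.05 and the centrosomal gene Pcnt by 0.56 ± 0.05. The basophil proteases Prss34 and Mcpt8 fell by 0.53 ± 0.08 and 0.50 ± 0.06, the lymphocyte activation marker Cd69 by 0.51 ± 0.04, the transcription factor gene Ets1 by 0.46 ± 0.06, Ier3 by 0.41 ± 0.05, Anxa1 by 0.32 ± 0.05 and Nfkbia, an inhibitor of NF-kB, by 0.23 ± 0.04. The rule for named genes required the same direction in 4 of 4 libraries, so this holds for each of them by selection. These sums were not balanced by class. Megakaryocyte-like cells were on average 16% of mutant and 12.4% of wild-type cells, with the mutant part larger in 4 of 4 libraries. Basophil/mast-like cells were 25.2% and 28.1%, with the mutant part larger in 1 of 4. Platelet and basophil genes can move with these shares. With each tag called apart, Cd68, Selenom, Ifi27, Tnfrsf18, Prss34, Mcpt8, Cd69, Ets1, Ier3, Anxa1 and Nfkbia had the opposite direction (Prss34 1.38, Mcpt8 1.22, Cd69 0.66), and none of them passed there. Of 14 alternatives, 8 kept the calls of Clu, Gp1bb, Cd68, Anxa1 and Nfkbia, and 6 that of Selenom.

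Dnmt3a itself was at 33.6 ± 3.53 CPM in mutant and 32.5 ± 4.0 CPM in wild-type cells (0.06 ± 0.05, adjusted p = 0.7). Ptprc, which encodes CD45, was at 109.5 ± 10.1 CPM in mutant and 124.5 ± 7.80 CPM in wild-type cells (-0.18 ± 0.03, adjusted p = 0.052). Ctse lies near Ptprc on chromosome 1 (131638314 to 131675507 against 138062859 to 138175756 in the mouse reference), and CD45.1 congenic mice carry sequence of another strain around Ptprc. Without the 822 genes within 30 Mb of Ptprc, 49 genes were called. Genotype and CD45 allele go together in every library. The mutation therefore cannot be told apart from other differences between the donors, for genes outside this region too.

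Of 13378 genes tested, 20 were higher and 31 lower in mutant cells in the edgeR fit with library as a block. In the megakaryocyte and platelet list, 2 of 19 measured genes rose, 16 when adjusted over the list alone, with a median of 0.49; camera called the list at 6.5e-23, and its adjusted p = 0.4 with an estimated correlation. In the NF-kB and TNF list, 3 of 23 fell (Cd69, Ier3 and Nfkbia), 10 when adjusted over the list alone, with a median of -0.16 (camera 4.8e-11; adjusted p = 0.18 with an estimated correlation). None of 47 G2 and M phase genes passed over all genes and 9 were lower when adjusted over the list alone, with a median of -0.10 (camera 4.4e-14; adjusted p = 0.58 with an estimated correlation). None of 29 long-term stem cell genes passed over all genes and 9 were higher when adjusted over the list alone, with a median of 0.38 (adjusted p = 0.74 with an estimated correlation). None of 20 lymphoid priming genes passed over all genes and 3 were lower when adjusted over the list alone, with a median of -0.34 (adjusted p = 0.66 with an estimated correlation). The granulocyte and monocyte list held 1 fallen gene of 25 (Anxa1) and the erythroid and heme list 1 risen gene of 30 (Aqp1), with 3 lower and 2 higher when adjusted over the list alone (adjusted p = 0.66 and 0.4 with an estimated correlation). No oxidative phosphorylation gene passed, although camera called complex I (median 0.05; adjusted p = 0.82 with an estimated correlation) and complexes II to V (0.04; adjusted p = 0.91 with an estimated correlation). The count of 51 genes was 24 without vehicle replicate 1, 131 without vehicle replicate 2, 23 without metformin replicate 1 and 88 without metformin replicate 2. It was 115 with DESeq2 and 12 without the library block. With each tag called apart, edgeR called 0 genes, with 2211 at an unadjusted p under 0.05 (DESeq2 was not run there).

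**Figure D2:**
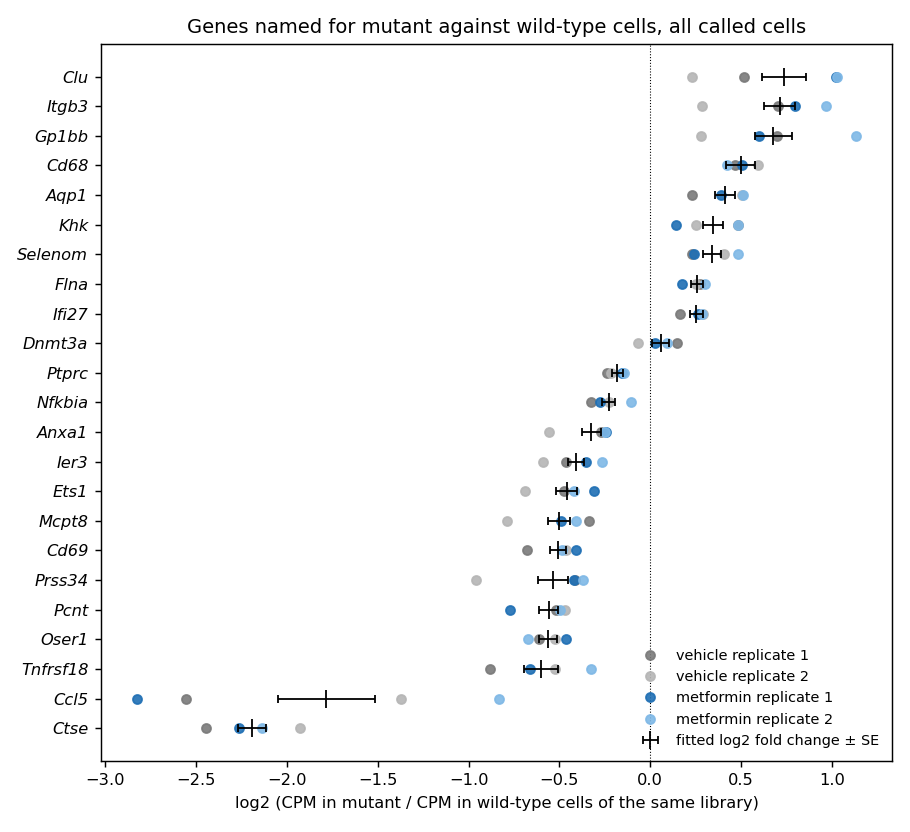
Log2 ratio of CPM in mutant over wild-type cells (x axis) for each gene named for this comparison (y axis), with 1 point per library and the fitted log2 fold change ± SE as a black mark. Ctse lies lowest at -2.19 and Clu highest at 0.74.

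Within each arm, the genotype difference in Ctse was -2.18 ± 0.11 in vehicle and -2.21 ± 0.12 in metformin. Genes that fell in mutant cells in vehicle included the proteases Prss34 (-0.67 ± 0.10) and Mcpt8 (-0.55 ± 0.08), Ms4a2, a chain of the IgE receptor (-0.56 ± 0.08), and the NF-kB and TNF genes Cd69 (-0.56 ± 0.06), Ier3 (-0.51 ± 0.05), the chemokine gene Ccl3 (-0.48 ± 0.06) and the deubiquitinase gene Tnfaip3 (-0.44 ± 0.05). Cdh1, which encodes E-cadherin, fell by 0.78 ± 0.11, Ets1 by 0.57 ± 0.08 and Oser1 by 0.55 ± 0.07. Of the 5 alternatives run for the arms, 1 kept the vehicle calls of Prss34 and Mcpt8, and 2 kept those of Ms4a2, Ccl3, Tnfaip3, Cdh1 and Ets1. The fold change went to -0.17 for Prss34, -0.06 for Mcpt8 and -0.15 for Ms4a2 at its smallest. In metformin, the platelet chemokine genes Ppbp (2.02 ± 0.20) and Pf4 (1.00 ± 0.12), the platelet receptor genes Clec1b (1.11 ± 0.10) and Treml1 (1.02 ± 0.11), and Mmrn1, a platelet granule protein gene (0.99 ± 0.14), rose in mutant relative to wild-type cells. Myom1 (1.23 ± 0.12), Bex4 (1.18 ± 0.11), the metalloproteinase inhibitor gene Timp3 (1.13 ± 0.13), Clu (1.02 ± 0.09) and Ehd3 (1.00 ± 0.17) also rose. Cxcl2, a neutrophil-attracting chemokine gene, fell by 0.86 ± 0.11, Pcnt by 0.64 ± 0.07, Gpc1 by 0.63 ± 0.11, Pdgfrb by 0.62 ± 0.10, Oser1 by 0.57 ± 0.07, Fkbp11 by 0.48 ± 0.07, Cd69 by 0.45 ± 0.06, Ier3 by 0.31 ± 0.05 and Clec4d by 0.38 ± 0.07. The call of Clec4d was kept in 0 of the 5 alternatives (adjusted p from 0.0577 to 0.469), those of Gpc1 and Pdgfrb in 2, and those of Mmrn1 and Ehd3 in 3.

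In vehicle, 8 genes were higher and 22 lower in mutant cells, and 4 of 23 NF-kB and TNF genes fell, 9 when adjusted over the list alone (median -0.19; adjusted p = 0.29 with an estimated correlation). In metformin, 53 genes were higher and 18 lower. There, 7 of 19 megakaryocyte and platelet genes rose, 16 when adjusted over the list alone (median 0.74; adjusted p = 0.41 with an estimated correlation), and 2 of 29 long-term stem cell genes rose, 15 when adjusted over the list alone (median 0.81; adjusted p = 0.7 with an estimated correlation). Megakaryocyte-like cells were 18.4% of mutant and 17.8% of wild-type cells in metformin replicate 1 and 14.9% and 7.94% in replicate 2, so the class share moves with this list. With equal cells per class the metformin values were 0.55 for Pf4, 0.82 for Treml1 and 2.61 for Ppbp, each of which passed, and within megakaryocyte-like cells 0.35 ± 0.04 for Pf4 and 1.47 ± 0.23 for Ppbp. Dnmt3a (0.06 ± 0.08 in vehicle, 0.06 ± 0.07 in metformin) and Ptprc (-0.21 ± 0.05 and -0.15 ± 0.05) did not pass in either arm. The vehicle count of 30 was 13 and 14 at posteriors of 0.9 and 0.5, and 19 with equal cells per class.

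Whether metformin changed the genotype difference was tested directly. Only Mtus2, a microtubule-associated tumor suppressor candidate gene, passed among 13378 genes (edgeR adjusted p = 5.2e-06; 534 genes at an unadjusted p under 0.05; DESeq2 called 3). Mtus2 stood at 17.5 and 15.2 CPM in wild-type cells of metformin replicates 1 and 2 and at 11.7 CPM in mutant cells of vehicle replicate 1. In the other 5 groups it was at 0.99 CPM or below. Tmem223, a gene chosen after its values were seen, had a related split, at 20.1 and 55.1 CPM in wild-type cells of metformin replicates 1 and 2 against 77.7 to 91.5 CPM in the other groups. Genes next in rank did not pass: Clec1b (1.05 ± 0.14, adjusted p = 0.2), Hoxb3os (1.63 ± 0.23, 0.2), Clec4d (-0.60 ± 0.09, 0.25) and the lowly expressed Atp9a (0.2), at 0.46, 3.04, 1.64 and 0.21 CPM in wild-type and 0.081, 0.14, 3.19 and 0.72 CPM in mutant cells of vehicle replicates 1 and 2 and metformin replicates 1 and 2. Dnmt3a (-0.0036 ± 0.10) and Ptprc (0.06 ± 0.07) did not pass. The megakaryocyte and platelet list had a median interaction of 0.36 with 8 of 19 genes higher when adjusted over the list alone and none over all genes (adjusted p = 0.82 with an estimated correlation). In HSC/MPP-like cells Mtus2 was again the sole gene to pass of 11317 (adjusted p = 2.37e-05; 344 genes at an unadjusted p under 0.05; DESeq2 called 1). The lowly expressed Trbc1 (8.25 CPM or below in every group; adjusted p = 0.11), Hoxb3os (1.91 ± 0.37, 0.54), Hoxb2 (2.08 ± 0.41, 0.54), Cox6a2 (-1.55 ± 0.31, 0.54), Dnmt3a (-0.38 ± 0.17, 1) and Ptprc (0.04 ± 0.11, 1) did not pass there. The count for all cells was 149 without metformin replicate 1, 21 without metformin replicate 2, 6 without vehicle replicate 1 and 4 without vehicle replicate 2. The HSC/MPP-like count was 113, 7, 17 and 14 in the same order. Without vehicle replicate 1, Mtus2 was not among the called genes in either set. Its log2 interaction in HSC/MPP-like cells still lay between -8.74 and -7.05 in the 9 alternatives, that fit included.

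**Figure D3:**
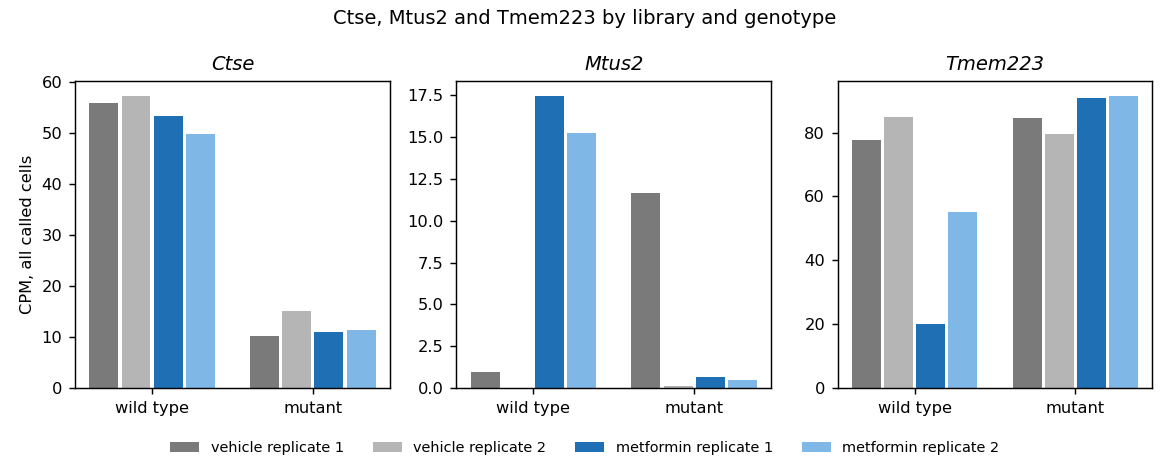
Expression of Ctse, Mtus2 and Tmem223 (y axes, CPM of summed UMIs over all called cells) by genotype (x axis), with 1 bar per library. Ctse separates the genotypes in every library, whereas Mtus2 is above 10 CPM in wild-type cells of both metformin libraries and in mutant cells of vehicle replicate 1.

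In HSC/MPP-like cells, mutant cells had more RNA of the stress-inducible regulator Nupr1 (1.59 ± 0.23; 43.7 ± 31.5 CPM in mutant and 14.3 ± 4.85 in wild-type cells, SD, n = 4), of the growth factor gene Clec11a (1.08 ± 0.17), and of Aldh1a1, a retinaldehyde dehydrogenase gene (0.87 ± 0.12). Apoe, an apolipoprotein gene, rose by 0.45 ± 0.07 and the MHC class I gene H2-Q7 by 0.41 ± 0.07. Ctse fell by 2.11 ± 0.10, Cd69 by 0.63 ± 0.09, the immunoglobulin heavy chain gene Ighm by 0.59 ± 0.11, Pcnt by 0.56 ± 0.07 and the mast cell protease gene Cpa3 by 0.35 ± 0.06. Of 11 alternatives, 5 kept the call of Ighm, 6 that of Apoe, 7 those of Cpa3 and Clec11a, and 8 that of Nupr1, which ranged from 0.97 to 1.99. Dnmt3a (-0.12 ± 0.09, adjusted p = 0.81) and Ptprc (-0.01 ± 0.05, adjusted p = 1) did not pass. Of 11317 genes, 11 were higher and 9 lower in mutant cells by edgeR, and 13 passed with DESeq2. None of 28 long-term stem cell genes passed over all genes and 4 were higher when adjusted over the list alone, with a median of 0.45 (camera 3.2e-11; adjusted p = 0.63 with an estimated correlation). In the lymphoid priming list 1 of 17 genes fell (Ighm), 6 when adjusted over the list alone (median -0.20; adjusted p = 0.63 with an estimated correlation). None of 47 G2 and M phase genes passed on either scale (median -0.10; camera 8.6e-09; adjusted p = 0.63 with an estimated correlation), and none of 35 interferon response genes did (median 0.17; adjusted p = 0.65 with an estimated correlation). The count of 20 was 12 without metformin replicate 1, 38 without metformin replicate 2 and 6 without the library block.

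Metformin was accompanied by lower immediate early transcription factor RNA in wild-type HSC/MPP-like cells. Klf2 fell by 2.08 ± 0.20 (from 318.3 ± 7.92 to 75.3 ± 43.1 CPM, SD, n = 2 per arm), Klf6 by 1.49 ± 0.15, Fos by 1.31 ± 0.09 (from 921.5 ± 47.5 to 374.2 ± 53.7 CPM), Fosb by 1.30 ± 0.12, Jun by 1.18 ± 0.07 and Jund by 1.13 ± 0.08, members of the Krüppel-like and AP-1 families. The phosphatase gene Dusp1 fell by 1.14 ± 0.10 and the stress phosphatase subunit Ppp1r15a by 0.62 ± 0.11. The MHC class II chaperone gene Cd74 fell by 1.04 ± 0.22, the MHC class I gene H2-D1 by 0.37 ± 0.07, Cd69 by 0.80 ± 0.11, Gimap6 by 0.74 ± 0.13, the carbonic anhydrase gene Car2 by 0.69 ± 0.09, Anxa1 by 0.55 ± 0.12, Ybey by 1.22 ± 0.27 and Tmem223 by 1.09 ± 0.24. The cell cycle inhibitor gene Cdkn1a rose by 0.77 ± 0.13, the galectin gene Lgals1 by 0.74 ± 0.09, the short-chain fatty acid receptor gene Ffar2 by 0.73 ± 0.16, Rab44 by 0.70 ± 0.15, the mitochondrial leucyl-tRNA synthetase gene Lars2 by 0.60 ± 0.11, the interferon-inducible Ifitm1 by 0.56 ± 0.10 and Cd52 by 0.54 ± 0.12. The calls of Cd52 (0.26 to 0.81) and Ybey were kept in 5 of 11 alternatives, those of Anxa1 and Ffar2 in 6, and those of Rab44 and Cd74 in 7. Mtus2 rose from 0.40 ± 0.56 to 17.1 ± 3.25 CPM, with the levels by library and genotype given above. Dnmt3a (0.38 ± 0.14, adjusted p = 0.35) and Ptprc (0.05 ± 0.10, adjusted p = 0.92) did not pass.

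Of 10703 genes, 10 were higher and 48 lower with metformin by edgeR, and 30 passed with DESeq2. In the immediate early and dissociation list, 15 of 23 measured genes fell, 19 when adjusted over the list alone, with a median of -0.90 (camera 1.6e-87; adjusted p = 0.15 with an estimated correlation). The MHC list had 2 fallen genes of 17, 7 when adjusted over the list alone (median -0.20; adjusted p = 0.42 with an estimated correlation; fry 0.0087). None of 24 long-term stem cell genes passed over all genes and 9 were lower when adjusted over the list alone (median -0.41; adjusted p = 0.57 with an estimated correlation). None of 30 MYC target genes (median 0.16) and none of 47 G2 and M phase genes (median 0.12) passed on either scale, although camera called both (adjusted p = 0.57 with an estimated correlation for each). None of 13 mitochondrially encoded genes passed over all genes and 4 were higher when adjusted over the list alone (median 0.16; adjusted p = 0.57 with an estimated correlation). The count of 58 was 94 without vehicle replicate 1 and 158 without vehicle replicate 2, and 30 at a genotype posterior of 0.9. Immediate early genes also respond to cell isolation, and the labels give no processing day per library.

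**Figure D4:**
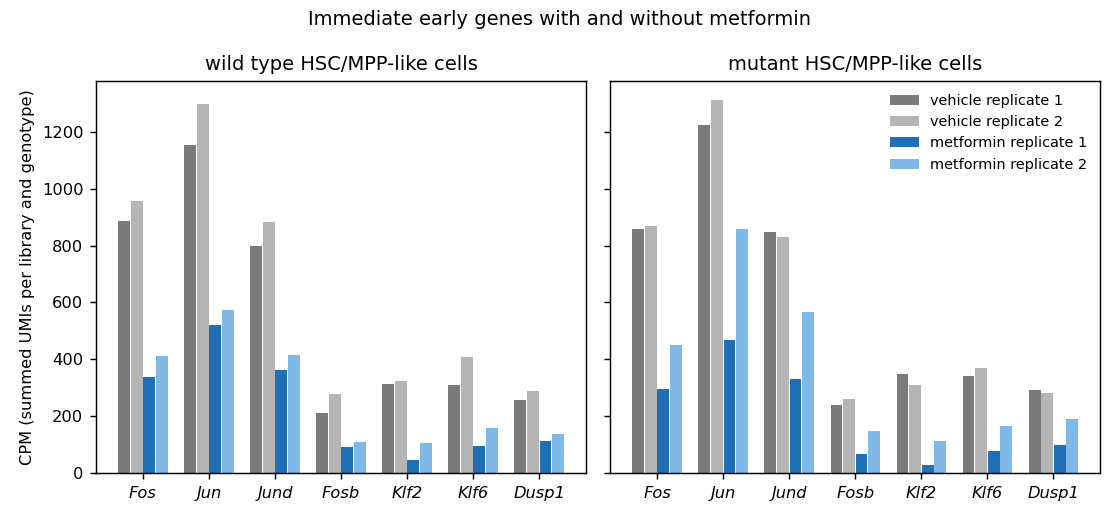
Expression of 7 immediate early genes (x axis) in wild-type (left) and mutant (right) HSC/MPP-like cells, in CPM of UMIs summed per library and genotype (y axis), with 1 bar per library. Each gene is lower in both metformin libraries than in both vehicle libraries, in either genotype; the 7 genes passed the test in wild-type cells, and the difference in response between the genotypes did not pass.

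In mutant HSC/MPP-like cells no gene passed with edgeR (0 of 12365; 1029 at an unadjusted p under 0.05), and DESeq2 called 24. The immediate early genes had fold changes near those in wild-type cells, with a wider spread between the metformin libraries: Fos -1.23 ± 0.15 (adjusted p = 0.099), Klf2 -2.18 ± 0.43 (0.42) and Jun -0.95 ± 0.22 (0.45), chosen as counterparts of the wild-type genes. The test of the genotype difference in response gave 0.07 ± 0.10 for Fos, -0.24 ± 0.17 for Klf2 and 0.17 ± 0.15 for Jun, each with an adjusted p of 1. None of 25 immediate early genes passed over all genes and 16 were lower when adjusted over the list alone (median -0.75; camera 1.7e-30; adjusted p = 0.83 with an estimated correlation). The genes with the smallest p, none of which passed, were Krtcap3 (6.41 ± 0.04 CPM in vehicle and 0.70 ± 0.04 in metformin; adjusted p = 0.095), the ubiquitin gene Ubb (-0.58 ± 0.06, 0.095), the chemokine gene Ccl4 (-0.75 ± 0.09, 0.095), the phosphatase gene Dusp2 (-0.61 ± 0.07, 0.099) and the small GTPase gene Rhob (-0.97 ± 0.12, 0.099). Dnmt3a (-0.0027 ± 0.10) and Ptprc (0.09 ± 0.08) did not pass. The count of 0 was 17 without vehicle replicate 1, 18 without vehicle replicate 2, 324 without metformin replicate 1 and 415 without metformin replicate 2.

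Over all called wild-type cells, metformin was accompanied by falls of Fos (-1.02 ± 0.13), Klf6 (-0.84 ± 0.12), Rhob (-0.81 ± 0.09), Dusp1 (-0.76 ± 0.10), Ier5 (-0.75 ± 0.09), Jun (-0.72 ± 0.09), Btg2 (-0.63 ± 0.08) and Jund (-0.63 ± 0.08). The glucocorticoid-induced gene Tsc22d3 fell by 0.78 ± 0.10 and the selenium-binding protein gene Selenbp1 by 0.70 ± 0.10. Cdkn1a rose by 0.66 ± 0.10, Cpt1a, which encodes the enzyme that commits fatty acids to mitochondrial oxidation, by 0.65 ± 0.10 (30.3 ± 3.03 to 48.3 ± 1.94 CPM), the NF-kB regulator Nfkbiz by 0.56 ± 0.09 and Ccl4 by 0.52 ± 0.08. With each tag called apart, Dusp1 (0.15), Ier5 (0.15), Jun (0.048), Btg2 (0.0042) and Cdkn1a (-0.0044) had the opposite direction and did not pass. The call of Ccl4 was kept in 7 of 14 alternatives and that of Selenbp1 in 7 of 13. Mtus2 rose from 0.49 ± 0.70 to 16.3 ± 1.59 CPM. Of 12566 genes, 7 were higher and 12 lower by edgeR, and 49 passed with DESeq2. In the immediate early list 7 of 25 genes fell, 17 when adjusted over the list alone (median -0.51; adjusted p = 0.28 with an estimated correlation), and in the NF-kB and TNF list 2 of 23 rose, 8 when adjusted over the list alone (median 0.29; adjusted p = 0.28 with an estimated correlation). None of 13 mitochondrially encoded genes passed over all genes and 9 were higher when adjusted over the list alone (median 0.28; adjusted p = 0.75 with an estimated correlation). Dnmt3a (0.21 ± 0.11) and Ptprc (0.10 ± 0.08) did not pass. The count of 19 was 226 without vehicle replicate 1, 306 without vehicle replicate 2, 6 without metformin replicate 1 and 31 without metformin replicate 2. With replicate number as a block edgeR called 0 genes, with 752 at an unadjusted p under 0.05, and with equal cells per class it called 107.

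Over all called mutant cells, 1 gene was higher and 1 lower with metformin among 14648 tested by edgeR, and DESeq2 called 311. The calcium-binding protein gene S100a6 rose by 0.77 ± 0.05 (from 47.0 ± 1.75 to 83.0 ± 0.50 CPM; adjusted p = 0.039), and Krtcap3, at low expression, fell by 2.90 ± 0.21 (from 3.96 ± 0.18 to 0.55 ± 0.13 CPM; adjusted p = 0.039). Ccl3 (0.86 ± 0.08), Clec4d (-0.85 ± 0.08) and Rhob (-0.87 ± 0.09) followed at an adjusted p of 0.097 and did not pass, nor did Dnmt3a (0.20 ± 0.06) or Ptprc (0.15 ± 0.06). None of 25 immediate early genes passed over all genes, and 16 were lower and 1 higher when adjusted over the list alone (median -0.47; adjusted p = 0.73 with an estimated correlation). None of 23 NF-kB and TNF genes passed over all genes and 8 were higher when adjusted over the list alone (median 0.32; adjusted p = 0.73 with an estimated correlation). None of 40 genes of complexes II to V passed on either scale (median -0.11; camera 1.3e-06; adjusted p = 0.73 with an estimated correlation). The count of 2 was 6 and 10 without vehicle replicates 1 and 2, and 30 and 88 without metformin replicates 1 and 2. The replicate block gave 31.

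Single classes had their own changes. A shift between the clusters of a class can move its sums, and so can RNA carried over from other classes, which was not estimated. In mutant basophil/mast-like cells the cytokine genes Tnf (1.51 ± 0.14) and Il6 (1.12 ± 0.11), Nfkbiz (1.08 ± 0.08) and the inhibitory receptor gene Lilrb4a (1.04 ± 0.10) rose with metformin, with 303 genes higher and 194 lower of 11178. The NF-kB and TNF list had a median of 0.56 there (adjusted p = 0.473 with an estimated correlation). Among these called cells the clusters had shifted. Cluster 7, led by Ccl6, Ccl4 and Ccl3, was 37.3% and 36.7% of them in vehicle and 47.8% and 48.5% in metformin. Over all kept cells of the class, in both genotypes and with or without a call, it held 590 of 1609 and 651 of 1824 in vehicle. In metformin it held 890 of 2371 and 657 of 1838, so such a shift was not seen there. Of the 10 leading genes of cluster 7 (median 2634 UMIs), 1 is a marker of this class, and at resolution 2 the cluster led by the same 3 genes (2158 cells) had no name. With equal cells per cluster 40 genes passed in place of 497, of which 28 were among the 497. Tnf (1.52 ± 0.24), Nfkbiz (0.70 ± 0.09) and Il6 (0.65 ± 0.11) passed, and Lilrb4a did not (0.46 ± 0.10, adjusted p = 0.0535). At a posterior of 0.5, 16 genes passed, with Tnf and Nfkbiz but without Il6 (adjusted p = 0.0587) and Lilrb4a (0.0742). In wild-type basophil/mast-like cells 3 were higher and 2 lower, among them Cxcl2 (1.19 ± 0.20), the itaconate enzyme gene Acod1 (1.31 ± 0.21) and Pf4, a gene of megakaryocytes (-1.36 ± 0.19). The test of the difference between genotypes called 6 genes in this class. In early granulocyte-monocyte progenitor-like cells Fos (-1.47 ± 0.12 in wild-type and -1.83 ± 0.08 in mutant cells), Klf2 (-2.11 ± 0.29 and -2.59 ± 0.23) and Jun (-1.24 ± 0.13 and -1.29 ± 0.14) fell, with 133 and 85 genes called. In megakaryocyte-like cells Fos fell (-1.4 ± 0.12 in wild-type and -1.5 ± 0.13 in mutant cells), and the protease inhibitor gene Serpina3g rose by 1.05 ± 0.12 and 1.10 ± 0.09, with 50 and 92 genes called. In early erythroid/megakaryocyte progenitor-like cells Fos fell (-1.23 ± 0.12 in wild-type and -1.17 ± 0.13 in mutant cells), with 10 and 9 genes called. Pf4 fell in the wild-type cells of this class too (-2.34 ± 0.29). In these 3 classes Fos passed in both genotypes also with equal cells per cluster, with values from -1.89 to -0.95, and at a posterior of 0.5. By genotype, Ctse fell in mutant cells in each of the 4 classes (-2.58 ± 0.11 in basophil/mast-like, -2.25 ± 0.12 in early granulocyte-monocyte progenitor-like, -1.74 ± 0.12 in early erythroid/megakaryocyte progenitor-like and -1.66 ± 0.17 in megakaryocyte-like cells). Pf4 rose by 0.26 ± 0.04 and Clu by 0.60 ± 0.10 in mutant megakaryocyte-like cells, where the megakaryocyte and platelet list had a median of 0.13 (adjusted p = 0.66 with an estimated correlation). The genes named per class are among the 12 with the smallest p. Monocyte progenitor-like cells were not tested, since 1 group held 35 cells.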

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

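The tests of Mtus2 across classes and in mature cells and the choice of Tmem223 came after their values were seen, and the interaction tests were planned.

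The genotype difference in Mtus2 changed with metformin in all called cells (edgeR adjusted p = 5.2e-06) and in HSC/MPP-like cells (2.37e-05). The call was lost without vehicle replicate 1 in either set. In HSC/MPP-like cells the log2 change stayed between -8.74 and -7.05 in the 9 alternatives, that fit included. Over all called cells it ranged from -10.04 to -1.88 in 12 alternatives. In HSC/MPP-like cells Mtus2 was at 19.4 and 14.8 CPM in wild-type cells of metformin replicates 1 and 2, at 11.7 CPM in mutant cells of vehicle replicate 1, and at 0.80 CPM or below in the other 5 groups. The same 3 groups were higher than the other 5 in 5 of 5 classes, with 8.12 CPM as the lowest high and 1.89 CPM as the highest low value. These classes make up the sums in which the 3 groups were seen, so this lends a strain or donor variant no separate support. In T/NK-like and plasma cell-like cells, which are outside these sums, Mtus2 had at most 8 UMIs per group, too few to decide. There it was at 12.7 and 9.57 CPM in wild-type cells of metformin replicates 1 and 2 but at 3.70 in mutant and 8.31 in wild-type cells of vehicle replicate 1. A response to metformin would leave mutant cells of vehicle replicate 1 low, and these were at 8.12 CPM or above in each class. An open candidate explanation is that the donors of the wild-type cells differed between the arms and those of the mutant cells between the vehicle libraries. In that case donor and treatment cannot be separated in wild-type cells, and donor differences enter the comparisons of mutant cells too.

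Single classes had further genes whose genotype difference changed with metformin. In basophil/mast-like cells 6 genes passed, among them the galectin gene Lgals3 (0.84 ± 0.14), the calcium-binding protein gene S100a6 (1.32 ± 0.22) and the neutrophil elastase gene Elane (-1.02 ± 0.17). Among called mutant cells the clusters of this class shifted with metformin, and these genes were not tested with equal cells per cluster. In early erythroid/megakaryocyte progenitor-like cells 2 passed, among them Pf4 (1.37 ± 0.24), which stood at 378.4 CPM in wild-type cells of vehicle replicate 2 and at 137.7 in those of replicate 1. In early granulocyte-monocyte progenitor-like cells 10 passed, among them Mtus2, S100a8 (0.95 ± 0.10), Tmem223 (1.62 ± 0.20) and the adhesion gene Vcam1 (1.31 ± 0.24). Here cluster 5 was 6.56% of wild-type cells in vehicle replicate 2. It was 39.0% in vehicle replicate 1 and 44.0% and 59.7% in metformin replicates 1 and 2. No interaction gene of any class was tested with equal cells per cluster. In megakaryocyte-like cells 4 passed, among them the actin regulator gene Dstn (0.82 ± 0.14), Tmem223 (1.53 ± 0.28) and Plac8 (-0.71 ± 0.13). In each class the genotype difference in metformin minus that in vehicle is given, from edgeR with 4 libraries.

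The genotype difference in the share of early erythroid/megakaryocyte progenitor-like cells was above 0 in both vehicle libraries and below 0 in both metformin libraries, with a change of -0.77 log2 odds. For early granulocyte-monocyte progenitor-like cells the order was the same, with a change of -0.65 log2 odds. With calls at a posterior of 0.5 these changes shrank to -0.25 and -0.26, and neither change was tested.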

How the results depend on the processing

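With calls within library and cluster, the lower mutant share with metformin kept its direction. The difference went from -37.3 (each tag called apart) to -33.8 percentage points (mixture weights), and from -38.8 to -31.3 when 1 library was left out. With each tag called apart within library and cluster, the shares themselves were 65.7% ± 24.2 (SD, n = 2) in vehicle and 28.3% ± 18.1 (n = 2) in metformin, with vehicle replicate 1 at 48.5% and metformin replicate 1 at 41.1%. With each tag called apart over a whole library, as planned, the direction was reversed. This gave 87 mutant and 570 wild-type cells in vehicle replicate 1 and 159 and 619 in replicate 2. In metformin replicates 1 and 2 it gave 221 and 193 mutant against 125 and 265 wild-type cells. The counts of called genes moved more. Posteriors of 0.9 and 0.5, mixture weights, the T/NK-like and plasma cell-like clusters, the crossed pairing, and equal cells per class for the interaction and for each arm were chosen after seeing the data. Where a direction or a count changed, the cause was not tested, except that the filter alternative tests more genes. Each tag called apart was not run in HSC/MPP-like cells, since metformin replicate 2 had 0 wild-type cells under it. Where 1 library of an arm remained, it was assumed to vary like the others. Depth limits the wild-type sums most, with 2007100 UMIs in HSC/MPP-like cells of vehicle replicate 2.

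Over all cells, the 51 genes of mutant against wild type became 115 with DESeq2, 574 without the filter on low counts, 140 at a posterior of 0.5, 166 with the T/NK-like and plasma cell-like clusters and 12 without the library block. RLE factors (54), a posterior of 0.9 (52), equal cells per class (43) and leaving out genes near Ptprc (49) changed the count little. The 30 genes in vehicle became 13 and 14 at posteriors of 0.9 and 0.5, 442 with the T/NK-like and plasma cell-like clusters and 19 with equal cells per class. The 71 in metformin became 118 with those clusters. The 1 gene of the interaction became 3 with DESeq2, 158 without the filter, 2 at posteriors of 0.9 and of 0.5, 69 with those clusters and 24 with equal cells per class. The 19 genes of metformin in wild-type cells became 49 with DESeq2, 289 without the filter, 66 and 299 at posteriors of 0.9 and 0.5, 107 with equal cells per class and 333 with a crossed pairing. With the replicate number as a block edgeR called 0 of them (752 at an unadjusted p under 0.05). Libraries of the same number deviated with a correlation across genes of -0.188 in wild-type and -0.0243 in mutant cells (-0.0379 and -0.0899 in HSC/MPP-like cells). This gave no sign of a pairing, but with 2 libraries per arm it cannot exclude one. The 2 genes of metformin in mutant cells became 311 with DESeq2, 890 without the filter, 1 and 25 at posteriors of 0.9 and 0.5, 1 with those clusters, 38 with equal cells per class, 31 with the replicate block and 60 with a crossed pairing. With each tag called apart, edgeR called 0 genes for genotype, the interaction, and metformin in wild-type and mutant cells (2211, 338, 1511 and 261 at an unadjusted p under 0.05; DESeq2 not run there).

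Among HSC/MPP-like cells, the 20 genotype genes became 13 with DESeq2, 167 without the filter and 6 without the library block. The 1 interaction gene became 33 without the filter and 2 at a posterior of 0.5. The 58 genes of metformin in wild-type cells became 30 with DESeq2, 149 without the filter, 30 and 112 at posteriors of 0.9 and 0.5, 109 with the replicate block and 137 with a crossed pairing. For metformin in mutant cells DESeq2 called 24 where edgeR called 0 (1029 at an unadjusted p under 0.05), and edgeR also called 0 with RLE factors, without the filter, at both posteriors and with the replicate block, whereas a crossed pairing called 124. Of the 27 gene lists, camera called 4 to 11 per comparison, and 0 with an estimated correlation in every comparison. A planted list passed in 1 of 8 comparisons with an estimated correlation, so that 0 says little. With fry it was 1 for metformin in wild-type HSC/MPP-like cells and 0 elsewhere.

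Without vehicle replicate 1, vehicle replicate 2, metformin replicate 1 and metformin replicate 2, in this order, the counts were 24, 131, 23 and 88 for genotype over all cells, 6, 4, 149 and 21 for the interaction, 226, 306, 6 and 31 for metformin in wild-type cells, and 6, 10, 30 and 88 in mutant cells. The HSC/MPP-like counts were 19, 26, 12 and 38 for genotype, 17, 14, 113 and 7 for the interaction, 94, 158, 43 and 47 for metformin in wild-type and 17, 18, 324 and 415 in mutant cells. Mtus2 was not among the interaction genes without vehicle replicate 1 in either set, nor with each tag called apart. Its log2 interaction ranged from -8.74 to -7.05 over the 9 alternatives in HSC/MPP-like cells and from -10.04 to -1.88 over the 12 in all cells.

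In the other classes, equal cells per cluster and a posterior of 0.5 were run after the data were seen. For metformin in mutant cells the count went from 497 to 40 and 16 in basophil/mast-like, from 9 to 27 and 349 in early erythroid/megakaryocyte progenitor-like, from 85 to 128 and 151 in early granulocyte-monocyte progenitor-like and from 92 to 44 and 201 in megakaryocyte-like cells. In wild-type cells it went from 5 to 32 and 8, from 10 to 10 and 91, from 133 to 131 and 215, and from 50 to 27 and 162 in the same order.

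Class shares changed direction as follows, in log2 odds. For mutant minus wild type, early erythroid/megakaryocyte progenitor-like cells went from 0.12 to -0.10 at a posterior of 0.5 and ranged from -0.044 to 0.33 with 1 library left out. Early granulocyte-monocyte progenitor-like cells ranged from -0.15 to 0.17 and monocyte progenitor-like cells from -0.063 to 0.68 with 1 library left out. For metformin minus vehicle in wild-type cells, a posterior of 0.5 gave 0.055 for early erythroid/megakaryocyte progenitor-like, -0.36 for megakaryocyte-like and 0.093 for monocyte progenitor-like cells, and resolution 2 gave -0.13 for megakaryocyte-like cells. With 1 library left out the ranges were -0.41 to 0.0055 for HSC/MPP-like, -0.0067 to 0.61 for basophil/mast-like, -0.63 to 0.70 for megakaryocyte-like and -1.17 to 0.65 for monocyte progenitor-like cells. In mutant cells, a posterior of 0.5 gave -0.30 for HSC/MPP-like, 0.22 for early granulocyte-monocyte progenitor-like, -0.28 for megakaryocyte-like and 0.15 for monocyte progenitor-like cells. There the ranges were -0.12 to 1.07 for HSC/MPP-like, -0.76 to 0.049 for early granulocyte-monocyte progenitor-like and -0.059 to 0.31 for megakaryocyte-like cells. The change of the genotype difference with metformin went from -0.77 to -0.25 at a posterior of 0.5 in early erythroid/megakaryocyte progenitor-like and from -0.65 to -0.26 in early granulocyte-monocyte progenitor-like cells, and reached -0.54 and -0.36 at the smallest with 1 library left out.

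The alternative values of single genes cover the named genes, Dnmt3a, Ptprc and the genes with the smallest p that did not pass. Of 1496 values, 1103 stayed on the same side of the threshold with the same direction, 268 no longer passed, 86 newly passed and 39 changed direction. For genes that had not passed, the same side means that they again did not pass. With each tag called apart, the genotype values of Cd68 (-1.31), Selenom (-0.11), Ifi27 (-0.19), Tnfrsf18 (0.71), Prss34 (1.38), Cd69 (0.66), Mcpt8 (1.22), Ets1 (1.42), Ier3 (0.78), Nfkbia (0.79), Anxa1 (0.24) and Ptprc (0.020) changed direction, as did Clec1b in the interaction (-1.44), Dnmt3a with metformin in mutant cells (-0.15), and Cdkn1a (-0.0044), Dusp1 (0.15), Ier5 (0.15), Jun (0.048) and Btg2 (0.0042) with metformin in wild-type cells. The other changes of direction were in Dnmt3a and Ptprc, which did not pass in any comparison as reported. Ptprc passed by genotype over all cells in some alternatives, with a lowest adjusted p of 0.0131 (0.000562 in vehicle and 0.0464 in metformin). Over all cells, Dnmt3a by genotype was -0.032 with equal cells per class (-0.049 in vehicle, -0.016 in metformin) and in metformin -0.0021 and -0.0025 at posteriors of 0.9 and 0.5. Its interaction was 0.0019 with DESeq2, 0.11 without vehicle replicate 1, 0.005 without metformin replicate 1 and 0.033 with equal cells per class. With the T/NK-like and plasma cell-like clusters, Ptprc with metformin in wild-type cells was -0.13. In HSC/MPP-like cells, Ptprc by genotype was 0.0042 without the filter, 0.0071 without vehicle replicate 2, and 0.0015 and 0.011 at posteriors of 0.9 and 0.5, its interaction -0.023 at a posterior of 0.5. With 1 library left out it ranged from -0.011 to 0.0071 by genotype, and from -0.034 (without vehicle replicate 1) to 0.13 with metformin in wild-type cells. Dnmt3a with metformin in mutant HSC/MPP-like cells was 0.028 without vehicle replicate 2, 0.036 without metformin replicate 1 and -0.061 without metformin replicate 2, and 0.020 and 0.023 at posteriors of 0.9 and 0.5.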

Other observations

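Metformin against vehicle was also compared without the tags, in both genotypes together, which was chosen after the data were seen and opens the late erythroid cells that had no genotype. In late erythroid-like cells the fatty acid desaturase genes Scd2 and Scd1 fell by 0.91 ± 0.08 and 0.70 ± 0.09 (edgeR, n = 2 libraries per arm). Scd2 went from 24.9 and 24.6 CPM in vehicle to 12.4 and 13.9 in metformin. Fos fell by 1.44 ± 0.12, Fosb by 1.29 ± 0.08, and Jun by 0.53 ± 0.06, and the nuclear matrix gene Banp rose by 0.68 ± 0.09 and the ubiquitin ligase gene Trim25 by 0.61 ± 0.07. In early erythroid cells without a call, the cyclin gene Ccnd1 rose by 1.20 ± 0.15 and Vps13c by 0.83 ± 0.11, and Klf2 fell by 2.03 ± 0.27, Fos by 1.11 ± 0.11 and Scd2 by 0.58 ± 0.07. In all HSC/MPP-like cells Fos fell by 1.19 ± 0.12, Rhob by 0.99 ± 0.10, Zfp36 by 0.71 ± 0.07, Ubb by 0.57 ± 0.05 and Dusp2 by 0.53 ± 0.05. Klf2 (-2.21 ± 0.41, edgeR adjusted p = 0.164), Klf6 (-1.49 ± 0.23, 0.13), Jun (-1.02 ± 0.14, 0.119) and Dusp1 (-1.06 ± 0.17, 0.13) did not pass there. These sets had 15 of 13046, 59 of 12880 and 6 of 13011 genes called, and DESeq2 called 358, 529 and 121. Pf4, a megakaryocyte gene, fell by 1.18 ± 0.14 in the late and 1.26 ± 0.13 in the early erythroid set, and the megakaryocyte and platelet list had medians of -0.49 and -0.37 there (adjusted p = 0.891 and 0.835 with an estimated correlation). Such genes of another cell type may come from carried-over RNA that differs between the arms, which was not tested. Pf4 was also called lower with metformin in wild-type basophil/mast-like and early erythroid/megakaryocyte progenitor-like cells (-1.36 and -2.34). Carried-over RNA was not estimated, so it can be part of the other changes in these sets and in other classes.

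All 13 mitochondrially encoded genes lay above 0 in each of these sets, with a median of 0.34 in late erythroid-like cells (adjusted p = 0.891 with an estimated correlation) and 0.50 in early erythroid cells (0.835). The median share of mitochondrial UMIs per cell was 1.78% and 1.66% in the metformin and 1.46% and 1.38% in the vehicle libraries, and late erythroid-like cells held 26380 and 29255 UMIs per cell in metformin against 35737 and 34898 in vehicle, so a difference in RNA quality between the arms was not excluded. Over all kept cells the megakaryocyte and platelet list had a median of -0.72, with 20 of 20 genes below 0 (adjusted p = 0.629 with an estimated correlation), beside the lower share of megakaryocyte-like cells. There edgeR called 1 gene of 17057, Igkv16-104 (0 and 0.0030 CPM in vehicle, 0.53 and 0.60 in metformin), and DESeq2 called 458. The erythroblast hormone gene Erfe (2.13 ± 0.18, adjusted p = 0.0614) did not pass. Cells of the mature clusters had a mutant share, from mixture weights, of 48.8% ± 8.40 in vehicle and 27.5% ± 2.36 in metformin for T/NK-like cells and of 31.3% ± 1.43 and 52.4% ± 14.3 for plasma cell-like cells (exact permutation p = 0.333 for each).

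For the mutant share and the immediate early genes, the tests of class mix, of animals or donors, of the tag selection and of handling were chosen after the results were seen, whereas the RNA test of the mutant share and the counts of splits were planned before their results. The mutant share was lower in the metformin libraries, where the tags also separated less. The RNA of 3 genes picked in vehicle (Ctse, Gm43305 and Gm47283), read over all cells of the called clusters without a tag, gave a median mutant share of 60.9% and 56.4% in the metformin libraries against 86.6% and 90.2% in vehicle. The level of each genotype came from the tag calls in vehicle, so the vehicle values restate those calls. The metformin values assume the same levels in that arm, which was not tested. If these levels hold, the metformin values argue against weaker tag separation as the whole cause, although Gm43305 alone gave 5.28% in metformin replicate 2. A different mix of classes is argued against by the 6 of 6 classes with a lower share in both metformin libraries. Differences between animals or donors unrelated to the treatment cannot be told apart from an effect of metformin with 2 libraries per arm (exact permutation p = 0.333). Shares at an earlier time were not analysed here, so no competitive advantage was tested.

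The immediate early genes were lower with metformin. Selection of cells by the tag call is argued against by a list median of -0.85 in all HSC/MPP-like cells without a tag (adjusted p = 0.799 with an estimated correlation). A difference in handling between the vehicle and the metformin libraries may lower the list in every cell type, and 12 of 12 cell sets had a median below 0, from -1.26 in mutant early granulocyte-monocyte progenitor-like to -0.11 in mutant basophil/mast-like cells. Carried-over RNA can add to this in any of the sets. A response of all these cells to metformin predicts the same, and the labels give no day of processing, so the 2 cannot be told apart.

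Other splits of the 8 sums of counts (4 libraries by 2 genotypes) were counted for the genotype comparisons. With the library as a block, these splits give 20 distinct fits, and 8 of the splits part the genotypes in all 4 libraries as the real one does. Both numbers are too few for a share under 0.05. For all cells, 1 of the 20 fits, the real one, called 51 genes or more, and the highest other called 8 (2 among the splits that part all 4 libraries). For HSC/MPP-like cells, 2 of the 20 called 20 genes or more, with 70 as the highest other (6 among the splits that part all 4 libraries). The fit with 70 genes parts the genotypes in vehicle replicate 1 and metformin replicate 2 alone. In these 2 libraries it compares the genotypes as the real split does, and what sets them apart from the others was not tested.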
